A study of Mus musculus with 59 samples.

How the data were processed

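RNA was sequenced from the pons of mice on a C57BL/6 background, with total RNA extracted with Trizol and purified on RNeasy columns, per the labels' protocols. The labels describe 59 samples, each from its own mouse as far as the series' design text says, and 37 of them have a column in the table analysed here. The other 22, which are the samples of deep cerebellar nuclei, further pons samples of wild-type mice and of mice homozygous for the duplicated knock-in, and 2 samples whose genotype is given as unknown, were not analysed here. Mapping to groups followed the labels. For 6 wild-type columns the column name matched 2 samples of the same genotype, so these columns were used as wild-type libraries without a sample number of their own. Their place in the first or the second set followed the arrangement of the table. Libraries are numbered here in the order of the column names within a genotype.

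The deposited values are FPKM (fragments scaled to transcript length and to mapped fragments) per gene and library, as computed by the authors. The submitters' processing notes name CASAVA 1.8.2, FastQC, Trimmomatic, TopHat2, DESeq and Cuffdiff and the mouse genome build mm8, without the role or order of each tool; gene symbols in the table include names from annotations newer than that build. The reference annotation used here (GENCODE M21) belongs to another build, so it served only for chromosome names, neighbouring genes and transcript lengths, and no coordinates are given. FPKM values keep no read totals, so the sequencing depth of each library is unknown and no counting error can be given. The precision therefore rests on the spread between libraries. FPKM summed to 488351 to 695249 per library in the first set and to 430083 to 560516 in the second, with 13563 to 13899 and 13665 to 13944 genes at 1 FPKM or more.

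The table has 41386 lines. Of these, 27 had a gene name turned into a date and were left out, and 132 lines repeated a symbol and were summed with the line of the same symbol, which left 41227 genes. An exact 0 in all libraries of a genotype beside clear values in another can be a failed estimate: Mbp, which encodes a major myelin protein, was listed at 0 in all wild-type and dupKIHet libraries of the second set and at 4613 to 5890 FPKM in all its other libraries. Genes of this kind (7 in the first set and 12 in the second) were left out of the tests of that set. The mitochondrial gene mt-Co1 was listed at 0 in all libraries of both sets. FPKM of near-identical family members, such as the metallothioneins and the class I histocompatibility genes, depend on how shared reads were split and are uncertain, as are overlapping and antisense genes, since no strand setting is given in the sources used here.

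The libraries form 2 sets. All 9 libraries of the first set came from males (Ddx3y at 23.6 to 32.6 FPKM, Xist at most 0.0176 FPKM), and all 28 of the second from females (Xist at 1.29 to 2.74 FPKM, Ddx3y at most 0.0215 FPKM). Each set was tested only within itself, so sex could not be added as a covariate. No pair of libraries held identical values; the correlation across genes of each library with its nearest library was 0.986 to 0.989 in the first set and 0.974 to 0.980 in the second.

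Values were transformed as log2(FPKM + 1) and genes with 1 FPKM or more in at least 3 libraries of a set were kept, which gave 14059 genes in the first set and 14802 in the second. For each set, limma 3.58.1 (lmFit and eBayes with a trend, in R 4.3.3) was fitted with one mean per genotype, so that all genotypes of a set shared the estimate of the spread. The 11 contrasts, 7 against wild-type and 4 between models, were tested two-sided with Benjamini-Hochberg adjustment over all genes kept, and a gene was called at an adjusted p under 0.05. All adjusted p-values of single genes come from limma. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM.

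Gene lists were fixed for cell types of the brainstem and neighbouring tissue, for stress, immune and metabolic pathways and for genes near or functionally tied to Atxn3. Of 27 lists, 24 were tested with camera at a preset correlation of 0.01 between genes, with adjustment over the lists within a contrast, and again with the correlation estimated from the data. Named genes followed a rule: Atxn3, up to 8 called genes with the largest increase and 8 with the largest decrease, up to 4 members of each list that camera called, and Acy3 and Tnfrsf13c. These 2 genes were included from recollection of the study's publication, which was not at hand, and no file or label used here names them. Its outline (oligodendrocyte genes changed in models with expanded ataxin-3 and not in the knockout) was also recalled when the lists and contrasts were fixed, so those choices were not blind to it. Genes of predicted models and small RNAs were passed over. Up to 10 genes called in the most contrasts against wild-type are named as shared genes. Apod, Anln, S100b, Mag, Myrf, the neurofilament genes, Lgmn in dupKIHom and the shared genes in further contrasts were named after their values were seen. The groups, tests, lists, naming rule and the alternatives listed first below were chosen before the data were examined.

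Overlap between contrasts against the same wild-type libraries was set beside 100 simulations of unchanged groups, beside the overlap of independent lists and beside the overlap when the 6 wild-type libraries were divided into 20 ordered pairs of groups of 3. Alternatives were another pseudocount (0.1), no filter, quantile normalization, a fit of only the 2 genotypes compared, the replicate number as a block and leaving out each library in turn. Alternatives added after the data were seen were fits without the 6 libraries numbered 1 of the second set or with a covariate for them, fits without libraries above 1000 FPKM of Ttr (a choroid plexus gene) or with Ttr as a covariate, and, for dupKIHet against KIHet, removal of a trend on transcript length. Other splits of the same libraries were counted for each contrast, with at most 100 drawn.

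The fits were tested on simulated data with 200 changed genes. Changes were planted only in genes of higher level, with noise drawn independently for each gene and library. Recovery at low FPKM or with effects shared by libraries was therefore not measured. In the simulation of dupKIHom against wild-type (14059 genes), 92% of genes changed by 1 on the log2 scale and 66% of those changed by 0.5 were recovered, and in that of KIHet against wild-type (14802 genes) 97% and 78%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.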

Results

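Spinocerebellar ataxia type 3 is caused by an expanded CAG repeat in ATXN3, which lengthens a polyglutamine tract in the deubiquitinase ataxin-3. Gene expression was compared by RNA sequencing in the pons, a brainstem region affected in the disease, of mice carrying expanded ataxin-3 or lacking the protein. The first set held 9 libraries from males, 3 wild-type, 3 homozygous for a knock-in allele with a duplicated repeat of 82 glutamines (dupKIHom), and 3 Atxn3 knockout (Atxn3KO). The second set held 28 libraries from females, 6 wild-type and 6 heterozygous for the duplicated knock-in (dupKIHet). It also held 4 heterozygous and 4 homozygous for a knock-in with a single repeat of 82 glutamines (KIHet and KIHom), and 4 each from transgenic mice with human ATXN3 of 84 or 15 glutamines (YACQ84 and YACQ15). Expression was given in FPKM, and the depth of each library is unknown. Libraries differed in Ttr, a transcript of the choroid plexus next to the pons, from 4.51 to 2909 FPKM in the first set and from 14.2 to 3125 FPKM in the second.

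Atxn3 itself was measured first. It stood at 7.04 ± 0.70 FPKM (SD, n = 3) in wild-type males and at 0.239 ± 0.083 FPKM (n = 3) in knockouts, and it fell by 2.70 on the log2 scale (limma adjusted p = 2.31e-06). In dupKIHom it rose 1.68-fold to 12.5 ± 1.79 FPKM (n = 3, limma adjusted p = 0.01), a call that did not pass without dupKIHom library 2 (adjusted p = 0.0578) or with a pseudocount of 0.1 (adjusted p = 0.0588). In the second set Atxn3 rose 1.59-fold in dupKIHet, from 7.05 ± 0.71 to 11.8 ± 1.31 FPKM (n = 6 each, limma adjusted p = 2.89e-06), with 6 of 6 dupKIHet libraries above all wild-type libraries. Adjusted over all genes, no difference from wild-type passed the test in KIHet (6.10 ± 0.62 FPKM, limma adjusted p = 0.461), KIHom (5.55 ± 0.08 FPKM, 0.118), YACQ84 (6.95 ± 1.20 FPKM, 1) or YACQ15 (8.99 ± 0.68 FPKM, 0.692), each with n = 4. Still, 4 of 4 KIHom libraries lay below all wild-type libraries and 4 of 4 YACQ15 libraries above them (limma unadjusted p = 0.00221 and 0.00119). In KIHet 3 of 4 and in YACQ84 1 of 4 lay below all wild-type libraries (0.0461 and 0.772). A change of Atxn3 in KIHom or YACQ15 is thus neither shown nor excluded. FPKM of mouse Atxn3 do not measure the human transgene except where its reads align to the mouse gene.

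**Figure D1:**
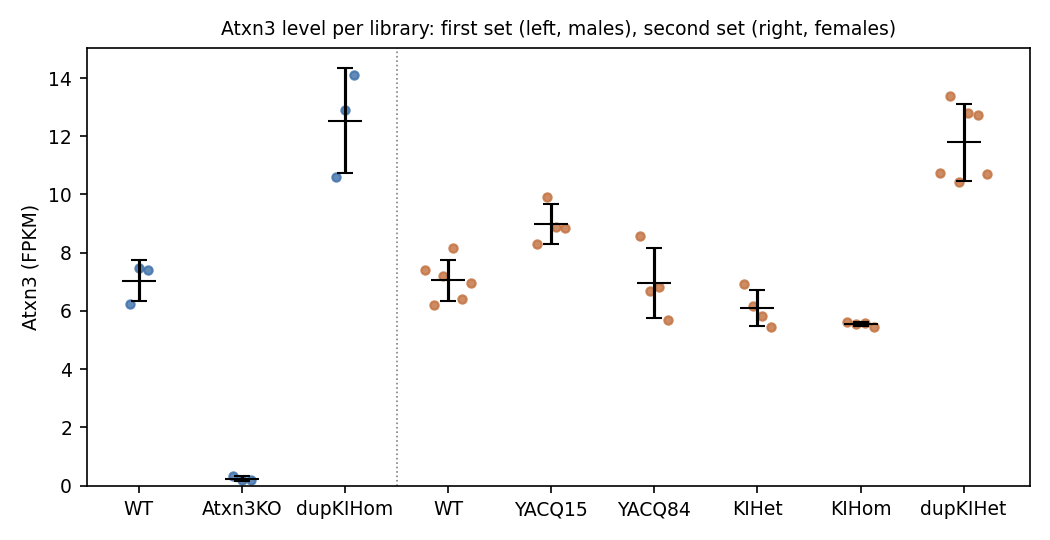
Atxn3 level in FPKM (vertical axis) of each library (points) by genotype, with the mean and SD of each genotype as bars; the first set is on the left and the second on the right. The knockout libraries average 0.239 FPKM, and the dupKIHom and dupKIHet libraries average 12.5 and 11.8 FPKM against about 7.04 and 7.05 FPKM in wild-type.

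The comparison of dupKIHom with wild-type asked how the pons responds to the duplicated knock-in on both alleles. Of 14059 genes tested, 230 changed, 68 higher and 162 lower. Among the largest decreases, Klk6, a kallikrein-related protease of oligodendrocytes, fell 2.84-fold from 70.0 ± 8.05 to 24.0 ± 3.01 FPKM (n = 3 each, limma adjusted p = 3.87e-05), and Serpinb1a, a serine protease inhibitor, fell 2.66-fold (adjusted p = 0.000239). Ppp2r3d, a regulatory subunit of protein phosphatase 2A, fell 2.79-fold (adjusted p = 0.000519), Etnppl, an astrocytic phospholipid enzyme, 2.47-fold (adjusted p = 0.0013) and Il33, a cytokine held in glial nuclei, 2.39-fold (adjusted p = 3.87e-05). Pyy, a peptide hormone gene, fell 2.26-fold (adjusted p = 0.0107) and passed in 5 of 6 fits that left out 1 library (0.0541 without dupKIHom library 2). Among the largest increases were Acy3, an aminoacylase, which rose 2.31-fold from 3.31 ± 0.04 to 8.97 ± 0.39 FPKM (adjusted p = 3.91e-05), and Chdh, the mitochondrial choline dehydrogenase, which rose 2.28-fold (adjusted p = 0.000574). Abca8a, a lipid transporter, rose 2.00-fold (adjusted p = 0.000913), Smoc1, a secreted calcium-binding protein, 1.96-fold (adjusted p = 0.0051) and the solute carrier Slc45a3 1.88-fold (adjusted p = 0.0016). Each of these 11 genes differed from the wild-type mean in the same direction in 3 of 3 dupKIHom libraries.

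Genes of mature oligodendrocytes and myelin did not move alike in dupKIHom. Of 35 measured, 13 fell, 1 rose and 21 did not pass, and with p-values adjusted over the list alone 18 fell and 2 rose. Car2, an oligodendrocyte carbonic anhydrase, fell 2.36-fold from 316 ± 9.13 to 133 ± 5.81 FPKM (n = 3 each, limma adjusted p = 3.15e-06). Ugt8a, which makes the myelin lipid galactosylceramide, fell 1.90-fold (adjusted p = 0.000105). The one that rose was the lipocalin Apod, by 0.60 on the log2 scale (adjusted p = 0.01, passing in 3 of 6 fits that left out 1 library, 0.0544 without dupKIHom library 1), while the adhesion protein Mag and the myelin regulator Myrf lay at -0.09 and -0.11 and did not pass. The list as a whole stood lower than other genes (camera adjusted p = 3.44e-18, but adjusted p = 0.215 with an estimated correlation). Among 10 transcription factors of the oligodendrocyte lineage, Sox8 rose 1.46-fold (adjusted p = 0.00245) and Zfp488, a repressor, by 0.59 on the log2 scale (adjusted p = 0.00605), with the other 8 not passing over all genes or adjusted over the list alone (camera adjusted p = 0.017, adjusted p = 0.344 with an estimated correlation). None of 19 precursor genes passed.

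**Figure D2:**
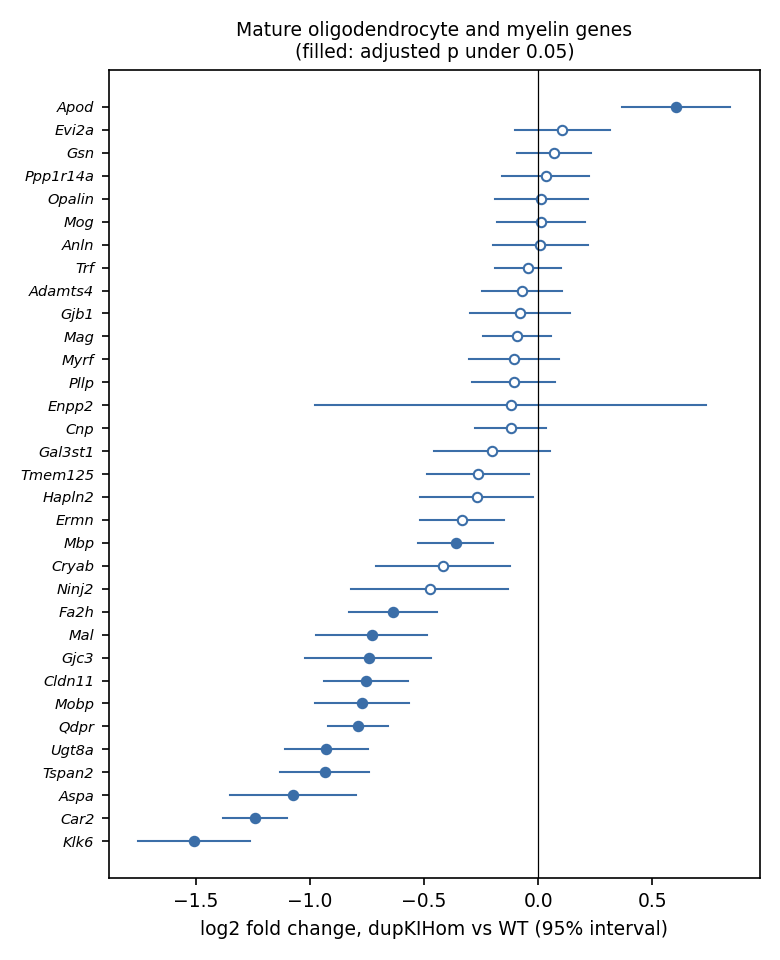
Log2 fold change (horizontal axis) between dupKIHom and wild-type for 33 of the 35 measured genes of mature oligodendrocytes and myelin, with 95% intervals as lines and filled points for genes with an adjusted p under 0.05. The filled points run from Klk6 at -1.51 to Apod at 0.60, while many members lie near 0.

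Astrocyte genes fell as well in dupKIHom. Of 20 measured, 10 fell and 10 did not pass, or 12 fell and 3 rose when adjusted over the list alone (camera adjusted p = 4.72e-09, adjusted p = 0.215 with an estimated correlation). Agt, the angiotensin precursor made by astrocytes, fell 2.28-fold from 64.1 ± 1.27 to 27.5 ± 1.35 FPKM (n = 3 each, limma adjusted p = 3.21e-05), and the glutamate transporter Slc1a2 fell 1.91-fold (adjusted p = 0.000261). Fgfr3, a growth factor receptor, and the gap-junction gene Gjb6 fell 1.65-fold and 1.59-fold (adjusted p = 0.00352 and 0.00361). Among endothelial and mural genes, the tight-junction gene Cldn5 fell 1.57-fold (adjusted p = 0.00427) and 17 of 19 did not pass, or 6 fell when adjusted over the list alone (camera adjusted p = 1.87e-07, adjusted p = 0.215 with an estimated correlation). Interferon-response genes stood higher as a list (camera adjusted p = 1.07e-09, adjusted p = 0.279 with an estimated correlation), with 1 of 20 passing over all genes and 9 adjusted over the list alone. That gene, Ifi27, rose 1.57-fold (adjusted p = 0.0296), a call that passed in 2 of 6 fits that left out 1 library (0.119 without dupKIHom library 3).

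Tnfrsf13c, a receptor of B cells, was looked at together with Acy3 because both were recalled as picked in the study's publication. It rose 1.81-fold in dupKIHom (n = 3 each, limma adjusted p = 0.0182), but the call passed in 1 of 6 fits that left out 1 library (adjusted p = 0.105 without dupKIHom library 1). If both genes were picked on these samples, their direction is not independent evidence. With 3 libraries per genotype, the count of 230 genes fell to 112, 115, 119, 119 and 138 without dupKIHom library 2, dupKIHom library 1, wild-type library 2, wild-type library 3 and wild-type library 1, and was 144 without the filter on low values.

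The knockout asked whether loss of ataxin-3 alone changes the pons. In Atxn3KO, 2 of 14059 genes changed, both lower: Atxn3 itself and Lgmn, a lysosomal cysteine protease whose gene lies on chromosome 12 as Atxn3 does. Lgmn fell 1.61-fold from 107 ± 5.78 to 66.2 ± 3.07 FPKM (n = 3 each, limma adjusted p = 0.00143) and was below all wild-type libraries in 3 of 3 knockouts. Acy3 (2.70 ± 0.18 FPKM, adjusted p = 0.733) and Il33 (log2 fold change -0.13, adjusted p = 0.86) did not pass. Mature oligodendrocyte genes stood lower as a list (camera adjusted p = 1.85e-18, adjusted p = 0.308 with an estimated correlation): none of 35 passed over all genes and 25 fell when adjusted over the list alone, with a median log2 fold change of -0.22. Choroid plexus genes stood higher as a list, with a median of 1.20 (camera adjusted p = 3.31e-10, adjusted p = 0.645 with an estimated correlation), and Ttr ranged from 17.6 to 2909 FPKM over the knockouts against 34.6 to 218 FPKM in wild-type. At an unadjusted p under 0.05, 908 genes differed. The count was 7 without wild-type library 3 and 8 without the 2 knockout libraries above 1000 FPKM of Ttr.

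Set against the knockout instead of wild-type, dupKIHom changed 175 genes, 78 higher and 97 lower, which compares expanded with absent ataxin-3 on the same background. Acy3 rose 2.69-fold (limma adjusted p = 1.79e-05), Chdh 2.06-fold (adjusted p = 0.00162) and Smoc1 2.07-fold (adjusted p = 0.00401). Agt fell 2.33-fold (adjusted p = 1.9e-05), Ppp2r3d 2.41-fold (adjusted p = 0.00162), Il33 2.18-fold (adjusted p = 0.000144) and Car2 2.14-fold (adjusted p = 5.72e-06). Mature oligodendrocyte genes showed 11 lower, 2 higher (Apod among them) and 22 not passing of 35, or 14 lower and 7 higher adjusted over the list alone (camera adjusted p = 0.000302, adjusted p = 0.588 with an estimated correlation). Astrocyte genes showed 9 lower and 1 higher of 20, or 11 lower and 2 higher adjusted over the list alone (camera adjusted p = 1.35e-07, adjusted p = 0.297 with an estimated correlation); the one that rose was S100b, which encodes a calcium-binding protein, by 0.45 on the log2 scale (adjusted p = 0.00483). Choroid plexus genes and genes of meninges and fibroblasts stood lower too (median log2 fold change -1.13 and -0.45, camera adjusted p = 5.08e-08 and 2.66e-06, adjusted p = 0.55 for both with an estimated correlation), with none of 16 and 12 passing over all genes or adjusted over the list alone. Sox8 rose 1.62-fold (adjusted p = 0.000721), and Lgmn rose by 0.68 on the log2 scale (adjusted p = 0.000343). The count was 63, 92 and 98 without dupKIHom libraries 1, 2 and 3, 113 and 109 without knockout libraries 1 and 3, 106 without the filter and 321 without the knockout libraries above 1000 FPKM of Ttr.

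In the second set, 375 of 14802 genes changed against wild-type with 1 duplicated knock-in allele (dupKIHet), 172 higher and 203 lower. That count was above those of the other 4 genotypes, but these had 4 libraries each against 6. In simulations, 87% of genes changed by 0.5 on the log2 scale were recovered for dupKIHet and 77% to 83% for the others. The counts were therefore not compared at like power. Etnppl fell 2.79-fold from 42.2 ± 4.88 to 14.7 ± 3.44 FPKM (n = 6 each, limma adjusted p = 5.91e-09) and Agt 2.74-fold from 60.3 ± 6.45 to 21.5 ± 3.04 FPKM (adjusted p = 1.18e-09). Nnat, a proteolipid of developing brain, fell 2.10-fold (adjusted p = 2.41e-06). The metallothioneins Mt2 and Mt1, which bind zinc and copper, fell by 1.04 and 0.85 on the log2 scale (adjusted p = 4.37e-06 and 4.15e-05), and Dao, which degrades D-serine, 2.00-fold (adjusted p = 3.86e-07). Chdh rose 2.09-fold from 2.01 ± 0.28 to 5.29 ± 0.56 FPKM (adjusted p = 2.65e-10), Acy3 1.70-fold (adjusted p = 3.18e-06) and Pcdh15, a protocadherin, 1.57-fold (adjusted p = 7.85e-06). Cdkn1c, a cyclin-dependent kinase inhibitor, rose 1.69-fold (adjusted p = 0.0139) and Abca8a 1.61-fold (adjusted p = 0.00826). All of these lay on the same side of the wild-type mean in 6 of 6 dupKIHet libraries. Tnfrsf13c, at 0.850 ± 0.204 FPKM, did not pass (adjusted p = 0.839).

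Astrocyte genes had the smallest camera p of the lists in dupKIHet. Of 20 measured, 11 fell and 9 did not pass, or 13 fell and 2 rose adjusted over the list alone, and the call held with an estimated correlation (camera adjusted p = 9.78e-25, and 1.39e-06 with the estimated correlation). Besides Agt, the glutamate transporter Slc1a2 fell 1.62-fold from 198 ± 15.1 to 122 ± 14.2 FPKM (n = 6 each, limma adjusted p = 3.71e-08), the gap-junction gene Gja1 1.48-fold (adjusted p = 2.15e-09) and the GABA transporter Slc6a11 1.46-fold (adjusted p = 3.32e-08). Mature oligodendrocyte genes also fell, 11 of 33 measured, or 13 adjusted over the list alone, and this call held too (camera adjusted p = 3.23e-12, and 0.0176 with the estimated correlation). Car2 fell 1.61-fold (adjusted p = 5.29e-07), Tspan2, a tetraspanin of oligodendrocytes, 1.37-fold (adjusted p = 4.15e-05) and Mal, a myelin proteolipid, 1.35-fold (adjusted p = 4.6e-05). Interferon-response genes stood higher as a list (camera adjusted p = 3.7e-09, adjusted p = 0.0673 with an estimated correlation), with 2 of 19 higher, or 9 adjusted over the list alone. These were Irf7 (1.48-fold, adjusted p = 0.0334) and Rtp4 (1.30-fold, adjusted p = 0.0201), which passed in 5 and 10 of 12 fits that left out 1 library, and not without wild-type library 2 (0.111 and 0.0662). Dbh, which makes noradrenaline, fell 1.59-fold (adjusted p = 0.0101). Endothelial and mural genes were called higher as a list, opposite to dupKIHom, but not with an estimated correlation. Flt1 rose 1.34-fold (limma adjusted p = 0.0238) and Esam 1.23-fold (0.0352). These 2 calls passed in 8 and 4 of 12 fits that left out 1 library (0.08 and 0.114 without wild-type library 2). Ttr ranged from 14.2 to 2470 FPKM in dupKIHet and from 27.7 to 643 FPKM in wild-type, and the choroid plexus list stood higher (median log2 fold change 0.82, camera adjusted p = 0.0447, adjusted p = 0.812 with an estimated correlation). The count of 375 was 222 when only these 2 genotypes were fitted and 813 with a covariate for the libraries numbered 1.

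**Figure D3:**
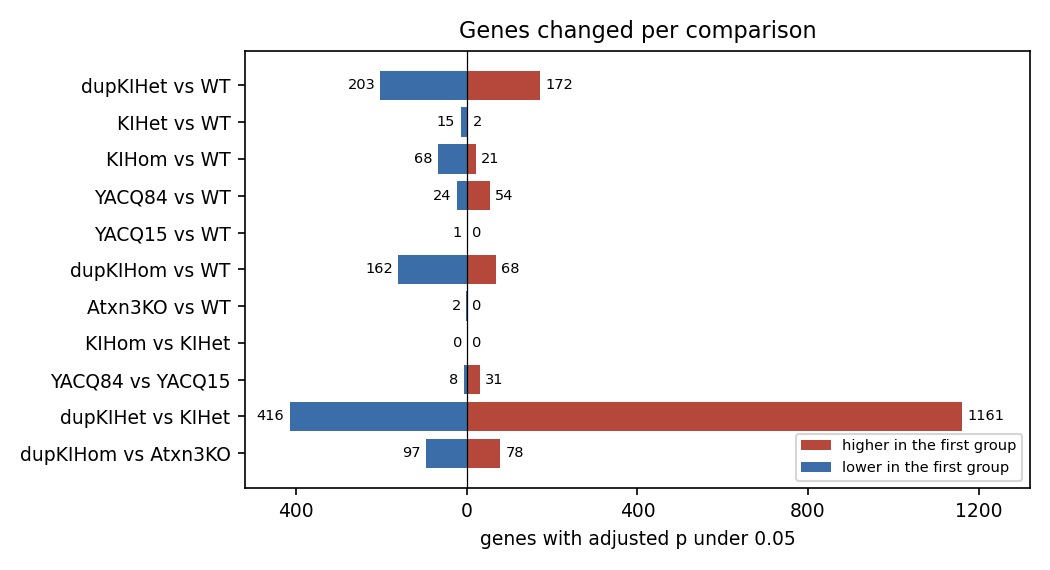
Number of genes with an adjusted p under 0.05 (horizontal axis) in each of the 11 comparisons (vertical axis), with genes higher in the first-named genotype to the right of 0 and lower ones to the left. The bars run from 0 genes for KIHom against KIHet to 1577 for dupKIHet against KIHet.

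The transgenic lines compared human ataxin-3 with an expanded or a normal repeat. In YACQ84, 78 genes changed against wild-type, 54 higher and 24 lower. Chdh rose 1.84-fold from 2.01 ± 0.28 (n = 6) to 4.55 ± 0.46 FPKM (n = 4, limma adjusted p = 1.88e-07), Acy3 1.58-fold (adjusted p = 0.000971), Slc45a3 1.57-fold (adjusted p = 0.00115), Pcdh15 1.53-fold (adjusted p = 0.000971) and Zfp488 1.39-fold (adjusted p = 0.00363). Il33 fell 1.56-fold from 95.5 ± 13.2 to 60.6 ± 5.68 FPKM (adjusted p = 0.00363), Car2 1.45-fold (adjusted p = 0.000971), Tspan2 1.34-fold (adjusted p = 0.00308) and Mal 1.31-fold (adjusted p = 0.00365), each in 4 of 4 libraries. Mature oligodendrocyte genes showed 6 lower of 33, or 12 adjusted over the list alone (camera adjusted p = 1.24e-06, adjusted p = 0.128 with an estimated correlation). Monoamine and cholinergic genes of the brainstem stood lower as a list, a call that held with an estimated correlation (camera adjusted p = 8.64e-11, and 0.00696 with the estimated correlation). Of its 19 genes Dbh alone fell, 1.63-fold (limma adjusted p = 0.0469, passing in 3 of 10 fits that left out 1 library, 0.268 without YACQ84 library 3), or 5 adjusted over the list alone. Astrocyte genes stood lower likewise (camera adjusted p = 3.41e-07, and 0.00696 with the estimated correlation), with 1 of 20 lower, or 3 adjusted over the list alone; Slc1a2 fell 1.23-fold (limma adjusted p = 0.0425), a call that passed in 2 of 10 fits that left out 1 library (0.192 without YACQ84 library 2). Tcea1-ps1, a pseudogene on chromosome 15, stood at 3.38 to 3.88 FPKM in 3 YACQ84 libraries, at 0.188 FPKM in YACQ84 library 4 and at 0.163 ± 0.074 FPKM in wild-type (limma adjusted p = 0.00179).

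YACQ15 differed from wild-type in 1 gene: Suds3, a subunit of the SIN3 histone deacetylase complex, fell 1.76-fold from 41.0 ± 5.81 (n = 6) to 22.9 ± 3.69 FPKM (n = 4, limma adjusted p = 0.0273). That call did not pass in 7 of the 10 fits that left out 1 library, with an adjusted p up to 0.114 without wild-type library 2. At an unadjusted p under 0.05, 665 genes differed. Camera called 13 lists in YACQ15, 9 lower and 4 higher, and none with an estimated correlation. Not all of these lists are named below. Chdh (log2 fold change 0.09), Il33 (0.12) and Acy3 (-0.19) did not pass, each with an adjusted p of 1. Genes of respiratory complexes I and V and cytosolic ribosomal protein genes stood lower as lists with none passing singly (camera adjusted p = 2.83e-06 and 3.1e-07, adjusted p = 0.489 for both with an estimated correlation). Choroid plexus genes stood higher, with none of 17 passing singly (median log2 fold change 0.75, camera adjusted p = 0.00144, adjusted p = 0.489 with an estimated correlation).

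Compared directly, YACQ84 and YACQ15 differed in 39 genes, 31 higher and 8 lower with the expanded repeat. Chdh was 1.73-fold higher in YACQ84, at 4.55 ± 0.46 against 2.21 ± 0.27 FPKM (n = 4 each, limma adjusted p = 1.17e-05), Acy3 by 0.85 on the log2 scale (adjusted p = 0.000196), Arrdc2, an arrestin-like adaptor, 1.79-fold (adjusted p = 0.000868) and Zfp488 1.42-fold (adjusted p = 0.0048). Il33 was 1.69-fold lower (adjusted p = 0.00173), Serpinb1a 1.65-fold (adjusted p = 0.0048), Car2 1.45-fold (adjusted p = 0.0027) and the metabotropic glutamate receptor gene Grm3 1.29-fold (adjusted p = 0.00622). Each of these genes lay beyond all YACQ15 libraries in 4 of 4 YACQ84 libraries. The monoamine and cholinergic list stood lower in YACQ84 (median log2 fold change -0.24, camera adjusted p = 1.1e-13, and 0.00399 with the estimated correlation). None of 19 passed over all genes and 7 adjusted over the list alone. Dbh of this list varied within genotypes and overlapped between them, from 4.84 to 10.9 FPKM in YACQ84 and from 8.85 to 11.8 FPKM in YACQ15. Of 9 lists called in this contrast, the monoamine and cholinergic list alone held with an estimated correlation. The astrocyte list, lower in YACQ84 against wild-type, did not, so no difference from YACQ15 was shown for it. Ttr ranged from 31.4 to 2143 FPKM in YACQ15 and from 28.7 to 578 FPKM in YACQ84, and the choroid plexus list stood lower in YACQ84 (median log2 fold change -0.85, camera adjusted p = 0.000621, adjusted p = 0.549 with an estimated correlation). These counts rest on the spread shared by all genotypes: fitted as 2 genotypes alone, YACQ84 changed 3 genes against wild-type and 0 against YACQ15, and without libraries above 1000 FPKM of Ttr the count against YACQ15 was 7. With a covariate for the libraries numbered 1 the counts were 207 against wild-type and 139 against YACQ15. With the replicate number as a block they were 0 and 2. Leaving out 1 library gave 31 to 60 genes against wild-type, lowest without YACQ84 library 3 (31) and library 1 (33). The count was 48, 48, 50, 48 and 50 without wild-type libraries 2, 3, 4 and 5 and YACQ84 library 2. Against YACQ15 it was 23 without YACQ84 library 3.

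The single-repeat knock-in was tested with 1 and with both alleles. KIHet changed 17 genes against wild-type, 2 higher and 15 lower. Sgk1, a kinase induced by glucocorticoids, fell 2.24-fold from 96.6 ± 19.4 (n = 6) to 42.7 ± 10.4 FPKM (n = 4, limma adjusted p = 0.000804), Klf2, a transcription factor of endothelium and immune cells, 1.94-fold (adjusted p = 0.00119) and Ddit4, a stress-induced inhibitor of mTOR signalling, 1.61-fold (adjusted p = 0.000804). Chdh rose 1.47-fold (adjusted p = 0.000804). These 4 genes lay beyond all wild-type libraries in 4 of 4 KIHet libraries. Lcn2, which encodes a siderophore-binding lipocalin, passed at 3.55-fold higher (adjusted p = 0.0499) but did so in 4 of 10 fits that left out 1 library (adjusted p = 0.24 without KIHet library 1). Cholesterol synthesis genes stood lower as a list, with none of 23 passing and 12 lower adjusted over the list alone (camera adjusted p = 4.82e-10, adjusted p = 0.0722 with an estimated correlation). Camera called 13 lists in KIHet, 4 lower and 9 higher, and none with an estimated correlation. The mature oligodendrocyte list was among those lower. Of its genes Tspan2 fell 1.32-fold (limma adjusted p = 0.0129), passing in 7 of 10 fits that left out 1 library (0.084 without KIHet library 3). Immediate early genes, the first to respond to neuronal activity, also stood lower, with none of 14 passing and 7 lower adjusted over the list alone (camera adjusted p = 4.45e-09, adjusted p = 0.199 with an estimated correlation). Cytosolic ribosomal protein genes and genes of respiratory complexes I and V stood higher, with none of 47 and 49 passing over all genes or adjusted over the list alone (camera adjusted p = 2.34e-09 and 3.71e-09, adjusted p of at least 0.486 for both with an estimated correlation). Choroid plexus genes stood higher too (median log2 fold change 0.53, camera adjusted p = 0.0019, adjusted p = 0.61 with an estimated correlation), with none of 17 passing over all genes or adjusted over the list alone, and Ttr ranged from 33.3 to 3125 FPKM in KIHet.

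KIHom changed 89 genes against wild-type, 21 higher and 68 lower. Chdh rose 1.70-fold (limma adjusted p = 3.59e-06), Acy3 1.65-fold (adjusted p = 0.000452) and Psat1, an enzyme of serine synthesis, 1.37-fold (adjusted p = 0.000331). Il33 fell 1.76-fold (adjusted p = 0.000452), Car2 1.46-fold (adjusted p = 0.000816), Tspan2 1.41-fold (adjusted p = 0.000568) and Mal 1.31-fold (adjusted p = 0.00589), each in 4 of 4 libraries. Mature oligodendrocyte genes showed 5 lower and 1 higher (Anln, passing in 2 of 10 fits that left out 1 library, adjusted p = 0.0793 without KIHom library 1) of 33, or 7 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00544, adjusted p = 0.541 with an estimated correlation). Cholesterol synthesis genes fell as a list, a call that held with an estimated correlation (camera adjusted p = 2.74e-13, and 0.0213 with the estimated correlation): 4 of 23 were lower over all genes and 16 adjusted over the list alone. Sqle, which encodes squalene epoxidase, fell 1.17-fold (limma adjusted p = 0.00969, passing in 9 of 10 fits that left out 1 library, 0.0535 without KIHom library 1). Insig1, a sensor of sterols, fell 1.28-fold and Mvd, of the mevalonate pathway, 1.40-fold, and these calls passed in 3 and 2 of 10 such fits (adjusted p = 0.117 for Insig1 without KIHom library 3 and 0.161 for Mvd without KIHom library 1). Endothelial and mural genes stood lower, with 2 of 20 passing, or 8 adjusted over the list alone (camera adjusted p = 1.14e-07, adjusted p = 0.152 with an estimated correlation). These were Pecam1 and Flt1, whose calls passed in 4 and 2 of 10 such fits (0.115 without KIHom library 1 and 0.147 without library 3).

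No gene differed between KIHom and KIHet under limma, where 333 genes had an unadjusted p under 0.05 and 0 passed in the fit of these 2 genotypes alone; Acy3, at 4.70 ± 0.49 against 3.14 ± 0.40 FPKM (n = 4 each), had an adjusted p of 1. Counts for both knock-ins against wild-type depended on the wild-type libraries and on the shared spread. For KIHom they were 239 and 173 without wild-type libraries 2 and 5, 32, 26, 24 and 32 without wild-type libraries 1, 3, 4 and 6, 22, 29, 19 and 27 without KIHom libraries 1 to 4, 6 with 2 genotypes fitted and 17 without libraries above 1000 FPKM of Ttr. For KIHet they were 138, 56, 10, 7 and 9 without wild-type libraries 2, 5, 3, 4 and 6, 5, 7 and 6 without KIHet libraries 1, 2 and 3, and 0 with 2 genotypes fitted. After quantile normalization 41.2% of the KIHom calls were higher, against 23.6% as deposited.

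The heterozygous knock-ins, duplicated and single, differed from each other in 1577 genes, 1161 higher and 416 lower in dupKIHet. Agt was 2.71-fold lower in dupKIHet, at 21.5 ± 3.04 (n = 6) against 59.5 ± 4.00 FPKM (n = 4, limma adjusted p = 5.07e-08), Etnppl 2.63-fold (adjusted p = 2.76e-07), Nnat 2.13-fold (adjusted p = 1.89e-05) and Mt2 2.08-fold (adjusted p = 3.85e-05). Astrocyte genes were lower as a list, 11 of 20 over all genes and 12 adjusted over the list alone, a call that held with an estimated correlation (camera adjusted p = 1.22e-12, and 0.000236 with the estimated correlation). Of the brainstem monoamine and cholinergic list, Dbh was lower 1.77-fold (limma adjusted p = 0.00238), as were Th, the first enzyme of catecholamine synthesis (log2 fold change -0.58, adjusted p = 0.00111), and the vesicular transporter gene Slc18a2 (-0.58, adjusted p = 0.00661). That list of 19 had 4 lower, or 6 adjusted over the list alone (camera adjusted p = 0.000419, adjusted p = 0.284 with an estimated correlation). Among the increases, the glycine receptor gene Glra1 was 1.84-fold higher in dupKIHet (adjusted p = 0.000767), the potassium channel gene Kcna2 1.74-fold (adjusted p = 0.00129) and the synaptic vesicle gene Sv2c 1.76-fold (adjusted p = 0.000235). Klf2 was 1.93-fold higher (adjusted p = 0.000146) and Sgk1 1.77-fold (adjusted p = 0.0021). Endothelial genes were higher, 9 of 20 over all genes and 11 adjusted over the list alone (camera adjusted p = 2.83e-06, adjusted p = 0.284 with an estimated correlation), with Flt1, a receptor for vascular growth factors, 1.86-fold (limma adjusted p = 2.99e-05) and Abcb1a, an efflux pump of the blood-brain barrier, 1.71-fold (adjusted p = 0.000201). Cytosolic ribosomal protein genes and genes of respiratory complexes I and V were lower, 6 of 47 and 7 of 49, or 6 and 10 adjusted over the list alone (camera adjusted p = 7.07e-12 and 8.88e-12, adjusted p = 0.469 for both with an estimated correlation). Interferon-response genes were higher in 6 of 19, or 7 adjusted over the list alone (camera adjusted p = 5.76e-05, adjusted p = 0.326 with an estimated correlation). The share of calls higher in dupKIHet was 73.6% as deposited, 54.6% after quantile normalization and 52.2% after a trend on transcript length was removed. The count was 885, 988 and 1028 without KIHet library 1, KIHet library 2 and dupKIHet library 5, 691 with 2 genotypes fitted and 3712 with a covariate for the libraries numbered 1.

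Several genes were called in the same direction in many models. Of the 7 contrasts against wild-type, Chdh (higher), Il33 and Tspan2 (both lower) were called in 5, namely dupKIHom, dupKIHet, KIHom, KIHet and YACQ84. Acy3 and Psat1 were higher and Mal, Pmp22, a myelin gene best known from peripheral nerve, Serpinb1a and Erbb2ip, a scaffold protein of ErbB2, were lower in 4. Some of these calls did not pass in every fit that left out 1 library. In KIHet, Il33 passed in 3 of 10 (adjusted p = 0.218 without KIHet library 1) and Tspan2 in 7 of 10 (0.084 without KIHet library 3), and in dupKIHom Psat1 passed in 2 of 6 (0.11 without dupKIHom library 2). In KIHom, Serpinb1a passed in 9 and Erbb2ip in 3 of 10 (0.0743 and 0.0967 without KIHom library 1). In YACQ84, Psat1 passed in 8 of 10 (0.0761 without YACQ84 library 1), Serpinb1a in 8 (0.106 without YACQ84 library 1) and Erbb2ip in 4 (0.162 without YACQ84 library 3). None of these 9 genes was called in YACQ15 or Atxn3KO. The models' differences were themselves tested for YACQ84 against YACQ15 and dupKIHom against Atxn3KO, and not for the other pairs with YACQ15 or Atxn3KO. Without predicted models and genes called in both directions, 22 genes were higher and 77 lower in exactly 2 contrasts. The counts were 6 and 14 in 3 contrasts, 5 and 8 in 4, and 1 and 2 in 5.

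**Figure D4:**
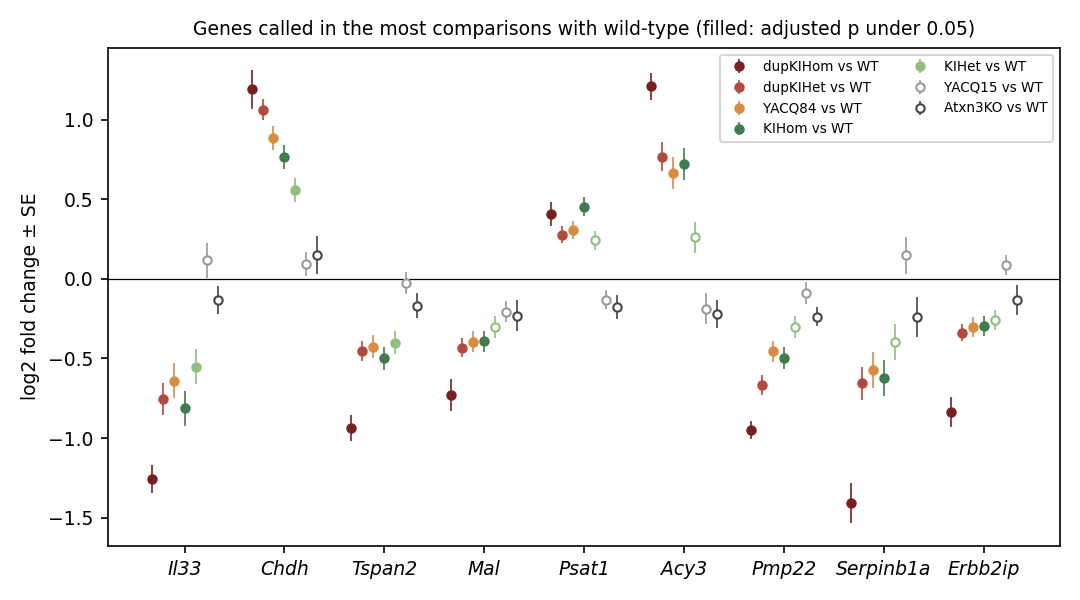
Log2 fold change (vertical axis) with its standard error for 9 of the genes called in the most contrasts against wild-type (horizontal axis), one point per contrast, filled where the adjusted p is under 0.05. Chdh runs from 0.56 in KIHet to 1.19 in dupKIHom among the filled points, and the YACQ15 and Atxn3KO points of these 9 genes are open.

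The count of shared calls was largest between the homozygous and heterozygous duplicated knock-in, which have separate wild-type libraries and were tested in different sexes. Among 12896 genes tested in both sets, 110 were called in the same direction in dupKIHom (215 calls) and dupKIHet (332 calls). Of these, 15 were higher and 95 lower, and none were called in opposite directions. Independent lists would share 0.721 and 2.16 (Fisher's exact p = 2.76e-16 and 7.97e-147). Fisher's test takes genes as independent, so these p-values are too small where genes vary together. dupKIHom shared 26 of the 86 calls of KIHom, 26 of the 69 of YACQ84 and 5 of the 15 of KIHet. It shared 0 with YACQ15, which had 1 call. Since such counts follow the number of calls in the other model, they do not rank how alike the models are. Within the second set, where the wild-type libraries are shared, dupKIHet and YACQ84 shared 51 calls (34 higher, 17 lower), dupKIHet and KIHom 28, KIHom and YACQ84 19 and KIHet and KIHom 9. Of these pairs only dupKIHet and KIHom had a call in opposite directions, 1 gene, Flt1, at 0.42 in dupKIHet and -0.52 in KIHom (limma adjusted p = 0.0238 and 0.0442, passing in 8 of 12 and 2 of 10 fits that left out 1 library). Simulated unchanged groups shared at most 1 call, but they held no changes to call. They do not show how many shared calls the common wild-type libraries add among lists of this size. Independent lists would share 0.627 higher and 0.329 lower for dupKIHet and YACQ84. With the wild-type libraries divided between the contrasts, the median overlap was 15 for dupKIHet and YACQ84, 9.5 for dupKIHet and KIHom, 7 for KIHom and YACQ84 and 1.5 for KIHet and KIHom. Each contrast then had only 3 wild-type libraries, which lowers power as well. The fall in overlap therefore does not measure what the common wild-type libraries added. Over all genes the covariance of log2 fold changes was 0.0219 for dupKIHet and YACQ84 against a simulated mean of 0.0193, and 0.0164 for dupKIHet and KIHom against 0.0189, both within the simulated range up to 0.038 and 0.0485. Of the gene lists, those of Atxn3 interactors, Atxn3 neighbours, oligodendrocyte precursors and p53 targets were called in none of the 11 contrasts.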

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

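Of the tests in this part, those on the oligodendrocyte share, on the other wild-type libraries and on the neighbours of Atxn3 were chosen after the result was seen.

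Of 35 oligodendrocyte genes, 13 fell in dupKIHom, 1 rose and 21 did not pass, with a median of -0.79 on the log2 scale over the 13 and -0.26 over all, and the list call was lost with an estimated correlation (camera adjusted p = 0.215). In the knockout the median over all was -0.22, with none passing limma over all genes but 25 lower adjusted over the list alone, against 18 in dupKIHom. If fewer oligodendrocytes had been in the tissue, members would have fallen by a like amount. However, 15 of 35 had a 95% interval wholly above a bound of -0.40, midway between 0 and the median of the 13. That bound comes from members picked for their fall, so intervals above it are partly built in. The median of all members is not picked so. Intervals of 11 lay wholly above it and of 12 wholly below it, which argues against a lower share as the whole cause. The authors' scaling is argued against by quantile normalization, after which 11 of the 13 were called lower, and a chance feature of the wild-type libraries by dupKIHet, where 11 of the 12 tested members were lower against other wild-type libraries. What lies behind the fall stays open, since no value here measures levels per cell, the pattern was found and tested on the same data, and a published outline of it was known beforehand.

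The direct contrast of dupKIHet and KIHet gave 1577 genes, more than either gave against wild-type. A transcript length bias is argued against as the whole cause, since 1488 genes were called after a length trend was removed, 1056 of them among the 1577, although the share of higher calls fell from 73.6% to 52.2%. Unequal amounts of choroid plexus are argued against likewise, with 1755 genes called with Ttr as a covariate, 1570 of them among the 1577. Lower glucocorticoid signalling in KIHet, which could be behind the fall of Sgk1 and Ddit4, stays open: of 8 other responsive genes 5 were lower in KIHet against wild-type (median -0.06, camera p = 0.6839 with an estimated correlation), 7 in dupKIHet (median -0.16, camera p = 0.158) and 6 in YACQ84 (median -0.04, camera p = 0.756), and in KIHom, where Sgk1 and Ddit4 also fell (-0.81 and -0.51, limma adjusted p = 0.0216 and 0.0127), 2 of the 8 were lower (median 0.08, camera p = 0.28). The KIHom calls of Sgk1 and Ddit4 passed in 5 and 8 of 10 fits that left out 1 library (limma adjusted p = 0.0793 and 0.0617 without KIHom library 1). Breeding, handling and day of dissection are not given in the labels and stay open.

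In Atxn3KO, Lgmn was lower and lies on the chromosome of Atxn3, so that sequence carried over with the targeted allele could explain it. Among 38 neighbours of Atxn3, 13.2% had an unadjusted p under 0.05 against 6.43% of other genes (one-sided Fisher's exact p = 0.09539, and 0.213 without Lgmn). The explanation is left open, because the neighbours are few.

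Other splits of the same libraries were counted for each contrast. In several contrasts a share under 0.05 of the splits, the real one included, gave as many genes as the real one. They were dupKIHet (375 genes, highest of the other splits 450, 2 of 100 splits), KIHom (89 against 9, 1 of 100) and YACQ84 (78 against 3, 1 of 100). They were also YACQ84 against YACQ15 (39 against 1, 1 of 35) and dupKIHet against KIHet (1577 against 1383, 1 of 100). The split with 450 genes set wild-type libraries 1 and 3 and dupKIHet libraries 1, 2, 3 and 5 against the rest. That with 1383 genes put dupKIHet libraries 4 and 6 with all KIHet libraries. Both parted dupKIHet libraries 4 and 6 from the others of their genotype, which points to a structure within dupKIHet. Without dupKIHet library 6 the counts were 471 and 2013. KIHet had a share under 0.05 too (17 against 60, 2 of 100). However, the split of wild-type library 2 and KIHet libraries 1 to 3 from the rest called several times the real count. That points to a structure of the samples. With only the 2 genotypes fitted KIHet had 0 calls, and the shares were not adjusted over the contrasts. Chance is therefore not excluded for KIHet. YACQ15 had a share above 0.05 (1 against 2, 9 of 100), and chance cannot be excluded there either. KIHom against KIHet had no call, so every split gave as many (0 against 36, 35 of 35) and the count decides nothing there. Splits of 3 against 3 libraries are too few for a share under 0.05: dupKIHom gave 230 against 1 (1 of 10), dupKIHom against Atxn3KO 175 against 1 (1 of 10) and Atxn3KO 2 against 7 (3 of 10).

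The contrasts between models with 39, 1577 and 175 genes (YACQ84 against YACQ15, dupKIHet against KIHet and dupKIHom against Atxn3KO) were singled out because the models' difference was itself tested.

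Single libraries far from the others of their genotype numbered 23 among 296 group values (7.77%), where the nominal rate is about 1 in 20, and 15 of the 23 were in libraries numbered 1. The mitochondrial transcript mt-Nd2 was high in libraries 1 of wild-type (10580 FPKM, others 5550 to 6340), dupKIHet (10950, others 5610 to 6670), KIHom (11450, others 6210 to 6650), YACQ84 (9654, others 4920 to 5410) and YACQ15 (10180, others 5570 to 6100), and KIHet library 1, though not past the rule for such gaps, was highest of all (12259, others 5717 to 7784). Ttr was high in wild-type library 1 (643.2 FPKM, others 27.7 to 223), KIHom library 1 (1874, others 33.6 to 52.1) and YACQ84 library 3 (578, others 28.7 to 65.3). In KIHet library 1, Lcn2 stood at 21.48 FPKM (others 3.07 to 4.9), Rps4x at 333.6 (others 317 to 318), Net1 at 3.911 (others 4.61 to 4.73) and Sik1 at 1.874 (others 2.19 to 2.25). Further high values were Atp5j2 in dupKIHet library 6 (164.7 FPKM, others 128 to 140), Etv1 in KIHom library 1 (34.36, others 29.2 to 29.7), Irf9 in KIHet library 4 (6.072, others 3.86 to 3.96), Lcn2 in dupKIHet library 3 (2.177, others 0.246 to 0.821), Mal in wild-type library 6 (219.8, others 161 to 181) and Pcdh15 in YACQ84 library 3 (7.324, others 5.22 to 5.44). Low values were Car2 in YACQ15 library 1 (232.8 FPKM, others 266 to 267), Itih3 in dupKIHet library 1 (23.08, others 30.2 to 33.8), Tcea1-ps1 in YACQ84 library 4 (0.1884, others 3.38 to 3.88), Tspan2 in KIHom library 3 (46.83, others 51.3 to 51.8) and the score of dupKIHom genes, described under the other observations, in YACQ15 library 1 (-0.03927, others 0.0686 to 0.0867).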

How the results depend on the processing

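Fits without the libraries numbered 1 or with a covariate for them, fits without libraries above 1000 FPKM of Ttr or with Ttr as a covariate, and removal of a length trend were chosen after the result was seen. Across these settings 1 call (dupKIHet against KIHet, length trend removed) had the opposite sign, and it was not called there. The causes of the differences below were not tested, except where fewer libraries entered a fit.

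Leaving out 1 library at a time gave these ranges: dupKIHet 257 to 471 genes, KIHet 5 to 138, KIHom 19 to 239, YACQ84 31 to 60, YACQ15 0 to 2, dupKIHom 112 to 160, Atxn3KO 2 to 7, KIHom against KIHet 0 to 0, YACQ84 against YACQ15 23 to 44, dupKIHet against KIHet 885 to 2013 and dupKIHom against Atxn3KO 63 to 182. For Atxn3 the log2 fold change ran from 0.63 to 0.70 in dupKIHet, -0.23 to -0.14 in KIHet, -0.32 to -0.25 in KIHom, -0.12 to 0.05 in YACQ84, 0.27 to 0.35 in YACQ15, 0.66 to 0.86 in dupKIHom, -2.77 to -2.65 in Atxn3KO, -0.16 to -0.06 for KIHom against KIHet, -0.43 to -0.26 for YACQ84 against YACQ15, 0.80 to 0.90 for dupKIHet against KIHet and 3.36 to 3.55 for dupKIHom against Atxn3KO. The dupKIHom call of Atxn3 was lost at a pseudocount of 0.1 (0.82, adjusted p = 0.0588) and without dupKIHom library 2 (0.72, adjusted p = 0.0578), and Atxn3 was called for YACQ84 against YACQ15 without the libraries numbered 1 (-0.47, adjusted p = 0.0368) and without YACQ84 library 1 (-0.43, adjusted p = 0.0392).

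With only the 2 genotypes compared, counts were 222 (dupKIHet), 0 (KIHet), 6 (KIHom), 3 (YACQ84), 0 (YACQ15), 0 (YACQ84 against YACQ15) and 691 (dupKIHet against KIHet). With the replicate number as a block they were 1 (KIHet), 1 (KIHom), 0 (YACQ84), 0 (YACQ15), 1 (Atxn3KO) and 2 (YACQ84 against YACQ15); libraries numbered 1 of the second set deviated together (r from 0.161 to 0.378 over 15 pairs), the other numbers did not pair throughout, and the closest match in another genotype had the same number for 2 of 9 and 13 of 28 libraries. Without the filter they were 10 (KIHet), 44 (KIHom), 2 (YACQ15), 144 (dupKIHom) and 106 (dupKIHom against Atxn3KO), and at a pseudocount of 0.1 YACQ15 had 2.

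Without the libraries numbered 1, counts were 7 (KIHet), 41 (KIHom), 47 (YACQ84), 2 (YACQ15) and 1 (KIHom against KIHet), and with a covariate for them 813 (dupKIHet), 130 (KIHet), 383 (KIHom), 207 (YACQ84), 139 (YACQ84 against YACQ15) and 3712 (dupKIHet against KIHet). Without libraries above 1000 FPKM of Ttr they were 10 (KIHet), 17 (KIHom), 0 (YACQ15), 8 (Atxn3KO), 7 (YACQ84 against YACQ15) and 321 (dupKIHom against Atxn3KO), and with Ttr as a covariate KIHet had 10.

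With an estimated correlation, fewer lists were called: 2 of 11 (dupKIHet), 0 of 13 (KIHet), 1 of 10 (KIHom), 2 of 10 (YACQ84), 0 of 13 (YACQ15), 0 of 9 (dupKIHom), 0 of 12 (Atxn3KO), 0 of 3 (KIHom against KIHet), 1 of 9 (YACQ84 against YACQ15), 1 of 13 (dupKIHet against KIHet) and 0 of 13 (dupKIHom against Atxn3KO). With the wild-type libraries divided, shared calls were 1.5 (dupKIHet and KIHet), 9.5 (dupKIHet and KIHom), 15 (dupKIHet and YACQ84), 1.5 (KIHet and KIHom), 1 (KIHet and YACQ84) and 7 (KIHom and YACQ84).

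Of 205 calls of named genes other than Atxn3, 201 were kept at a pseudocount of 0.1, 201 with Ttr as a covariate, 180 after quantile normalization, 165 without the filter, 144 without libraries above 1000 FPKM of Ttr, 118 in every fit that left out 1 library, 108 with only the 2 genotypes and 105 with the block. In the second set's 152 calls, 110 were kept without the libraries numbered 1 and 152 with a covariate for them. Depth is unknown, so its limit on genes of low FPKM could not be given. Sex as a covariate was not run, since each set holds 1 sex.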

Other observations

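The tests of the score below were chosen after the result was seen.

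A score was built in the first set and read in the second, to ask whether the response of dupKIHom depends on the expanded repeat. It was the mean log2 level of 62 genes higher in dupKIHom less that of 151 genes lower, without Atxn3 and its neighbours, and set to 0 in the wild-type libraries of the second set (0 ± 0.0721, SD, n = 6). It stood at 0.585 ± 0.0508 in dupKIHet (n = 6, exact permutation p = 0.00216 against wild-type), 0.424 ± 0.0949 in YACQ84 (n = 4, p = 0.00476), 0.324 ± 0.0708 in KIHom (n = 4, p = 0.00476), 0.163 ± 0.0894 in KIHet (n = 4, p = 0.0143) and 0.0476 ± 0.0584 in YACQ15 (n = 4, p = 0.305), all two-sided. The values 0.00216 and 0.00476 are the smallest that these permutations can give. Of the dupKIHom calls, 110 were already called alike in dupKIHet, 26 each in KIHom and YACQ84 and 5 in KIHet. These scores thus partly restate that overlap. YACQ84 exceeded YACQ15 by 0.376 in 4 of 4 libraries (exact permutation p = 0.0286, the smallest that 70 permutations can give, and 0.0381 adjusted over 8 tests). Unless stated otherwise, the permutations of this score exchanged all libraries freely. They take no account of the libraries numbered 1, which deviated together. Of the 213 genes, 27 were called in a contrast of the transgenic lines, so their direction was already known, and with the other 186 YACQ84 still exceeded YACQ15, by 0.276 (exact permutation p = 0.0286, the smallest possible). The response may thus reach beyond the genes called in YACQ84, but whether it depends on the repeat stays open, because the repeat goes with the line and the amount of human transgene was not measured. KIHom exceeded KIHet by 0.16 (exact permutation p = 0.0571, and 0.05 with libraries numbered 1 exchanged only with each other, the smallest that 40 such permutations can give), a difference neither shown nor excluded.

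The 3 neurofilament genes, which encode axonal proteins and were named after their values were seen, were lower in dupKIHom: Nefl by -0.39, Nefm by -0.43 and Nefh by -0.37 on the log2 scale (limma adjusted p = 0.0121, 0.0156 and 0.0393, in n = 3 libraries each). These calls were not stable and passed in 2, 1 and 0 of 6 fits that left out 1 library, with an adjusted p of 0.0664 for Nefl without wild-type library 2, 0.0698 for Nefm without dupKIHom library 2 and 0.161 for Nefh without dupKIHom library 3.

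In YACQ15, 7 of the 8 glucocorticoid-responsive genes used for KIHet stood lower, with a median of -0.26 on the log2 scale (camera p = 0.00301 with an estimated correlation, 1 of 5 contrasts looked at and not adjusted for that), and in dupKIHet 7 of the 8 were lower too (median -0.16, camera p = 0.158 with an estimated correlation).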
